A study of Mus musculus with 140 samples.

How the data were processed

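The series holds RNA sequencing of blood and tibialis anterior muscle of WT mice and of mdx mice with different numbers of Utrn copies; tissue, genotype, age, mouse and hour of collection were taken from the labels. Per the labels, blood was drawn from the tail of fasted mice, total RNA was depleted of globin transcripts in blood, and paired-end libraries were made. The submitters' processing notes name STAR, Cufflinks and the genome build mm10 without giving versions or roles. The authors deposited, for each of the 140 libraries, the counts of fragments per gene for 24451 genes, together with counts of fragments that were not assigned to a gene, which made up a median of 41.6% of a library in blood and 32.9% in muscle. They also deposited, for the whole series, log2 CPM (log2 of counts scaled to library size) for 10038 genes. Its columns were checked against the counts: over 9927 genes the SD of the difference from log2 CPM of the counts had a median of 0.127, but 2 columns stood apart, that of WT blood replicate 3 at 24 weeks, which is identical to that of mdx/utrn+/- blood replicate 3 at 24 weeks although their counts differ (SD 0.650), and that of mdx/utrn-/- blood replicate 2 (SD 0.916). The counts were therefore used throughout, and the log2 CPM only as an alternative for muscle. No 2 libraries of a group had identical counts.

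Libraries were grouped by tissue, genotype and age, and lists, named genes and tests were fixed before the data were examined. Comparisons used edgeR 4.0.16 in R 4.3.3 with TMM scaling, genes kept by filterByExpr, and quasi-likelihood F tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 31 muscle libraries of 30-week WT, mdx, mdx/utrn+/+ and mdx/utrn+/- mice were fitted together (14631 genes), with 1 library per mouse. The 8 mdx/utrn-/- muscles at 6 weeks were fitted with the 8 mdx/utrn+/+ muscles at 30 weeks (14683 genes). Blood counts were summed per mouse over weeks 6, 12 and 18 for the 20 mice with at least 2 of these libraries (14823 genes). Each week was also fitted alone (13692, 13665, 13782, 13873 and 13609 genes in weeks 6, 12, 18, 24 and 30), with the mean of the 3 dystrophic genotypes set against WT, and the 6-week fit held the mdx/utrn-/- libraries as well. Change with age used the 30 libraries of 15 mice with blood at 6 and 30 weeks, with the mouse as a paired block, and an interaction of age with dystrophic genotype. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM are counts scaled to library size after TMM scaling within the fit, or over all libraries of a tissue where a value is given for single libraries.

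Named genes were Dmd and Utrn, the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean of at least 5 CPM and an established symbol, and up to 3 called members of each gene list with the smallest p, or the first member where none was called. E030030I06Rik, Cd59b and Fv1 in the muscle comparisons of dystrophic genotypes, Naalad2 and 3110070M22Rik in mdx blood, and Rab6b and Snap25 outside their comparisons, were named after their values were seen. The 31 gene lists covered muscle regeneration, fibrosis, fibre types, metabolism, the dystrophin complex, the neuromuscular junction, stress, immune and blood cells, vessels, fat, nerve, the circadian clock and possible admixed tissue; 24 were tested in muscle. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry, which tests whether the members of a list move one way and does not compare them with other genes. With the preset correlation 30 of the 31 lists were called in at least 1 comparison, and with an estimated correlation 1 call was kept, the interferon response with age in dystrophic blood. The keratinocyte and skin list, the exception, had 1 called member over all comparisons, Perp with age in WT blood (1.72). Lists of 24 brain genes and of bone and tendon genes were added after the data were seen. Positions are from GENCODE M21 and RefSeq annotation of GRCm38, the assembly that mm10 denotes.

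Overlaps of calls were set beside the number that independence gives, simulated groups, and splits of the WT libraries. On simulated counts with the same libraries, edgeR recovered 50 to 91 of 100 genes changed 2-fold and 88 to 100 of those changed 4-fold, with 3 to 14 false calls; DESeq2 made 14 to 41 false calls, limma-voom 61 and limma-trend 12. Of 20 unchanged sets camera called 0 and fry 0 to 4.

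Alternatives were RLE scaling in edgeR, DESeq2 1.42.0, no filter on low counts, the cohort or the hour of collection as a covariate, parts of the mice, all ages, only the compared groups, limma-trend on the log2 CPM of the authors, limma-voom with the mouse as a random block (consensus correlations 0.108 and 0.106), removal of haemoglobin genes, and each blood mouse left out in turn. Haemoglobin genes held at most 0.00136% of gene fragments, so their removal changes little by construction. After seeing the data, fits were added without the libraries with abundant brain transcripts, without 1 library of doubtful genotype, and without Rn45s. Splits of the samples into other groups of the same sizes were fitted for every comparison, at most 100 each. Single-library values were compared by Dixon's range test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and version 1.17.8 of the R package data.table were used for the results files and figures. No library was left out of the main comparisons; the 9 muscle libraries of ages without a group of mice were used in the fits of all ages alone.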

Results

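Gene expression was measured by RNA sequencing in 140 libraries from 49 mice. These are 92 libraries of tail blood from 25 mice and 48 libraries of the tibialis anterior, a muscle of the lower hind leg, from 48 mice, with 24 mice in both tissues. WT mice were compared with mdx mice, which carry a Dmd mutation and make no full-length dystrophin, and with mdx mice that carry both, 1 or no intact copies of Utrn, the gene of the related protein utrophin (mdx/utrn+/+, mdx/utrn+/- and mdx/utrn-/-). Muscle of 30-week mice came from 7 WT, 8 mdx, 8 mdx/utrn+/+ and 8 mdx/utrn+/- mice, and the 8 mdx/utrn-/- muscles were taken at 6 weeks. The other 9 muscle libraries were from WT (1 at 12 and 1 at 18 weeks), mdx (2 at 12 weeks), mdx/utrn+/+ (2 at 18 weeks) and mdx/utrn+/- mice (1 each at 6, 12 and 18 weeks). The same mice were bled repeatedly. In weeks 6, 12, 18, 24 and 30 there were 5 WT blood libraries each, 5, 4, 4, 2 and 4 of mdx, 5, 5, 5, 3 and 3 of mdx/utrn+/+, and 4, 5, 5, 4 and 4 of mdx/utrn+/-. There were 5 blood libraries of mdx/utrn-/- mice, taken at 6 weeks. The fragments counted to genes ranged from 1906342 to 86725733 per library in blood and from 9786739 to 73047372 in muscle. The smallest blood libraries were mdx/utrn+/- replicate 1 at 12 weeks (1906342), mdx/utrn+/+ replicate 3 at 18 weeks (3073420), WT replicate 1 at 30 weeks (3309612) and WT replicate 4 at 18 weeks (4288840).

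Dmd (GRCm38 chromosome X, 82948870 to 85206141) and Utrn (chromosome 10, 12382188 to 12869365) are the genes by which the genotypes differ. In 30-week muscle Dmd was at 202 ± 19.5 CPM in WT (mean ± SD, n = 7), 53.4 ± 8.26 in mdx, 45.2 ± 4.17 in mdx/utrn+/+ and 44.5 ± 6.19 in mdx/utrn+/- mice (n = 8 each). Its log2 fold changes against WT, with their standard errors, were -1.92 ± 0.09, -2.16 ± 0.10 and -2.18 ± 0.10 (adjusted p = 1.14e-14, 5.20e-16 and 4.00e-16 by edgeR). Over all 48 muscle libraries the WT libraries lay between 180.3 and 252.9 CPM and the libraries of all other genotypes between 31.8 and 84.4 CPM. Utrn was at 57.6 ± 10.2 CPM in WT, 57.9 ± 11.8 in mdx, 49.2 ± 5.39 in mdx/utrn+/+ and 38.4 ± 6.86 in mdx/utrn+/- muscle. It was lower in mdx/utrn+/- than in WT muscle by edgeR (log2 fold change -0.58 ± 0.12, adjusted p = 2.73e-04), and -0.36 ± 0.12 against mdx/utrn+/+ did not pass (adjusted p = 0.499). In 6-week mdx/utrn-/- muscle Utrn was at 33.4 ± 3.98 CPM, against 57.5 ± 5.94 in 30-week mdx/utrn+/+ muscle scaled in the same fit (-0.78 ± 0.08, adjusted p = 2.04e-05). The labels do not say which part of Utrn the knockout removes, and counts over the whole gene need not fall to 0. In blood Utrn was at 47.4 ± 7.32 CPM in mdx/utrn-/- (n = 5) and 42.0 ± 5.20 in mdx/utrn+/+ mice (n = 5) at 6 weeks, and Dmd was near 0.426 ± 0.0959 CPM in WT blood.

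**Figure D1:**
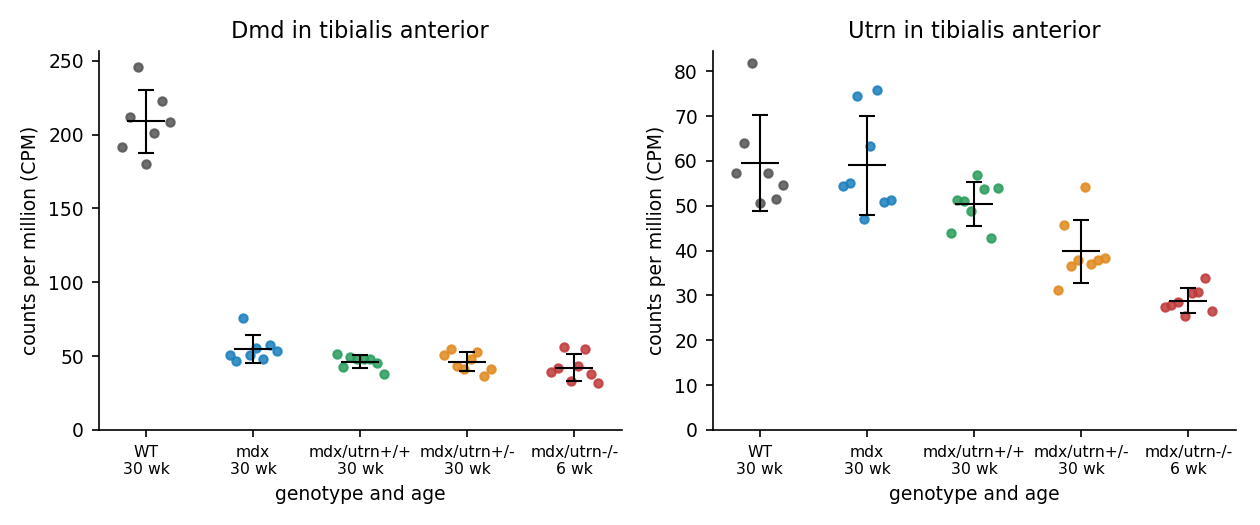
Dmd and Utrn in CPM in each library of 30-week muscle and of 6-week mdx/utrn-/- muscle, by genotype. Points are libraries, bars the mean and its SD. Dmd of the WT libraries lies at 180.3 CPM or higher and that of every plotted dystrophic library at 75.7 CPM or lower.

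What differs in dystrophic muscle was asked at 30 weeks, by comparing mdx, mdx/utrn+/+ and mdx/utrn+/- muscle with WT. Values are given in this order of genotypes, and changes are log2 fold changes with their standard error after ±. Genes of muscle regeneration rose. Of the 23 measured members of the myogenic regeneration list, 16, 19 and 18 rose and none fell (adjusted p = 0.199, 0.104 and 0.0802 with an estimated correlation). The log2 fold changes of Myh3, the embryonic myosin heavy chain, were 4.97 ± 0.47, 5.27 ± 0.47 and 5.61 ± 0.48, above every WT library in 8 of 8 libraries of each genotype. Chrng, a subunit of the fetal acetylcholine receptor, rose by 5.55, 5.84 and 6.03, and Tmem8c (myomaker, needed for myoblast fusion) by 8.23 ± 0.64 and 8.39 ± 0.65 in mdx/utrn+/+ and mdx/utrn+/- muscle. The cell cycle inhibitor gene Cdkn2a had the largest rise among named genes in mdx/utrn+/- muscle (8.97 ± 0.45, adjusted p = 9.55e-15 by edgeR). Of 25 cell cycle genes, 20, 21 and 22 rose and 1 fell (adjusted p = 0.230, 0.185 and 0.196 with an estimated correlation), among them Mki67 (3.64, 4.61 and 4.01). The extracellular matrix and fibrosis list rose in 25, 25 and 28 of 31 members, 25, 27 and 30 when adjusted over the list alone, and none fell (adjusted p = 0.287, 0.189 and 0.110 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 5.66, 6.29 and 6.05, and the collagen gene Col3a1 by 2.38, 2.97 and 3.12.

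Genes of immune cells rose in the same muscles. Of 27 macrophage genes, 26 rose in each genotype and none fell (median log2 fold changes 2.93, 3.27 and 3.31; adjusted p = 0.124, 0.104 and 0.0802 with an estimated correlation). Trem2, a lipid receptor of macrophages, rose by 5.09 ± 0.46, 5.56 ± 0.46 and 5.42 ± 0.46, and Ctss, a lysosomal protease, by 4.43, 4.78 and 4.76. Mmp12, the macrophage elastase, rose by 8.11 and 8.37 in mdx/utrn+/+ and mdx/utrn+/- muscle. All 11 measured genes of MHC class II antigen presentation rose (adjusted p = 0.163, 0.104 and 0.0802 with an estimated correlation), with H2-DMa at 1.84, 2.12 and 2.14. Of 18 complement genes, 14, 13 and 16 rose and 1, 1 and none fell (adjusted p = 0.230, 0.185 and 0.0802 with an estimated correlation), among them C1qa (2.34, 2.77 and 2.83). The type I interferon response list rose in 21, 26 and 21 of 30 members, and 1, none and 1 fell (adjusted p = 0.504, 0.319 and 0.476 with an estimated correlation). Oas2, a sensor of viral RNA, rose by 1.59 ± 0.26, 2.19 ± 0.27 and 1.94 ± 0.27. Of 15 T cell genes, 8, 11 and 8 rose, Il7r by 3.18, 3.56 and 3.54 (adjusted p = 0.503, 0.339 and 0.410 with an estimated correlation). Of 14 neutrophil genes, 7, 7 and 10 rose and 1 fell (adjusted p = 0.435, 0.339 and 0.341 with an estimated correlation), and of 14 B cell genes 5, 4 and 5 rose.

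Genes of energy metabolism fell. Of 26 genes of fatty acid oxidation, 25 fell in each genotype and none rose (median log2 fold changes -0.96, -1.01 and -0.92; adjusted p = 0.124, 0.104 and 0.110 with an estimated correlation). Acsl1, which activates long-chain fatty acids, changed by -1.39 ± 0.17, -1.53 ± 0.17 and -1.48 ± 0.17, below every WT library in 8 of 8 libraries of each genotype. Of 40 genes of oxidative phosphorylation, 35, 38 and 35 fell and none rose (adjusted p = 0.230, 0.266 and 0.341 with an estimated correlation); Sdhb, a subunit of succinate dehydrogenase, changed by -0.85, -0.79 and -0.80. Of 20 glycolysis genes, 8, 9 and 6 fell and 1, Pgm1, rose (adjusted p = 0.465, 0.511 and 0.618 with an estimated correlation); the hexokinase gene Hk2 changed by -1.32, -1.48 and -1.67. Of 19 fast fibre genes, 10, 7 and 4 fell and none rose (adjusted p = 0.435, 0.511 and 0.653 with an estimated correlation), among them Myh4, the myosin of the fastest fibres (-0.91, -0.90 and -0.70). Without the libraries with abundant brain transcripts, given below, 10 fast fibre genes fell in mdx and 13 in mdx/utrn+/- muscle, and 2 rose in each. Of the glycolysis genes 8 and 12 then fell in these genotypes. The numbers of falls in these 2 lists therefore do not rank the genotypes. The list of slow and oxidative fibres was split, with 5 of 16 members up in each genotype and 8, 6 and 5 down; the slow troponin gene Tnni1 rose by 3.78, 4.22 and 4.33. Its median was -0.53 and -0.35 in mdx/utrn+/+ and mdx/utrn+/- muscle, while its mean was 0.16 and 0.21.

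Of 15 endothelial genes, 12, 12 and 6 fell and none, none and 1 rose (adjusted p = 0.230, 0.266 and 0.440 with an estimated correlation), with the endothelial phosphatase gene Ptprb at -0.89, -1.06 and -0.86. Of 15 adipocyte genes, 10, 10 and 5 fell and 2, 1 and 1 rose (adjusted p = 0.230, 0.267 and 0.532 with an estimated correlation); Cidea, a lipid droplet gene, rose by 2.32, 2.04 and 2.42. In the list of denervation and the neuromuscular junction 13, 11 and 10 of 21 members rose and 2 fell (adjusted p = 0.287, 0.185 and 0.0802 with an estimated correlation), with the transcription factor gene Dach2 at -4.87, -4.72 and -4.99. In the dystrophin-associated complex 7, 8 and 8 of 20 members rose and 1 fell, Bgn (biglycan) by 1.36, 1.85 and 1.99 and Nos1, the neuronal nitric oxide synthase, at -2.14 and -2.30 in mdx/utrn+/+ and mdx/utrn+/- muscle. In the atrophy and stress list 4 of 20 members rose and 3, 5 and 1 fell, with Mstn (myostatin, which limits muscle growth) at -2.16, -2.38 and -2.23 and the metallothionein gene Mt2 at 4.90, 5.13 and 5.09. The Schwann cell and myelin list had 5, 2 and none of 13 members up and 5, 4 and 4 down (adjusted p = 0.402, 0.339 and 0.341 with an estimated correlation). Of 18 immediate early genes 10, 3 and 3 rose and 4 fell, of 18 circadian genes 3, 2 and 2 rose and 3, 5 and 5 fell, and of 12 erythroid genes 5, 6 and 3 rose and 2, 4 and 3 fell.

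Of 14631 genes tested by edgeR, 7520 passed in mdx muscle (4899 higher and 2621 lower), 7349 in mdx/utrn+/+ (4368 and 2981) and 6328 in mdx/utrn+/- muscle (3444 and 2884). The median log2 fold change of all tested genes was 0.16 in mdx and 0.11 in mdx/utrn+/+ muscle. In 3 of the 30-week libraries (mdx replicates 5 and 6 and mdx/utrn+/+ replicate 5) neuronal and glial transcripts were abundant: 24 brain genes summed to 8730, 5095 and 5976 CPM there and to at most 741 CPM in WT. All 8 genes with the largest rise in mdx muscle were transcripts known from nervous or endocrine tissue, led by Snap25 (synaptic, 10.06 ± 2.73), which was at -0.58 without these libraries. Without them 6683 genes passed in mdx (3595 higher and 3088 lower), 8349 in mdx/utrn+/+ and 8656 in mdx/utrn+/- muscle. In each genotype 26 of 27 macrophage genes and 20 of 23 regeneration genes were then higher and 25 of 26 genes of fatty acid oxidation lower. Tmem8c and Cdkn2a then rose the most among named genes in mdx muscle (8.10 and 7.91), and 9, 10 and 9 of the 13 Schwann cell and myelin genes fell. In mice without blood libraries, which are fewer, 974, 2560 and 1860 genes passed, and in mice with blood libraries 4070 passed in mdx/utrn+/+ muscle.

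**Figure D2:**
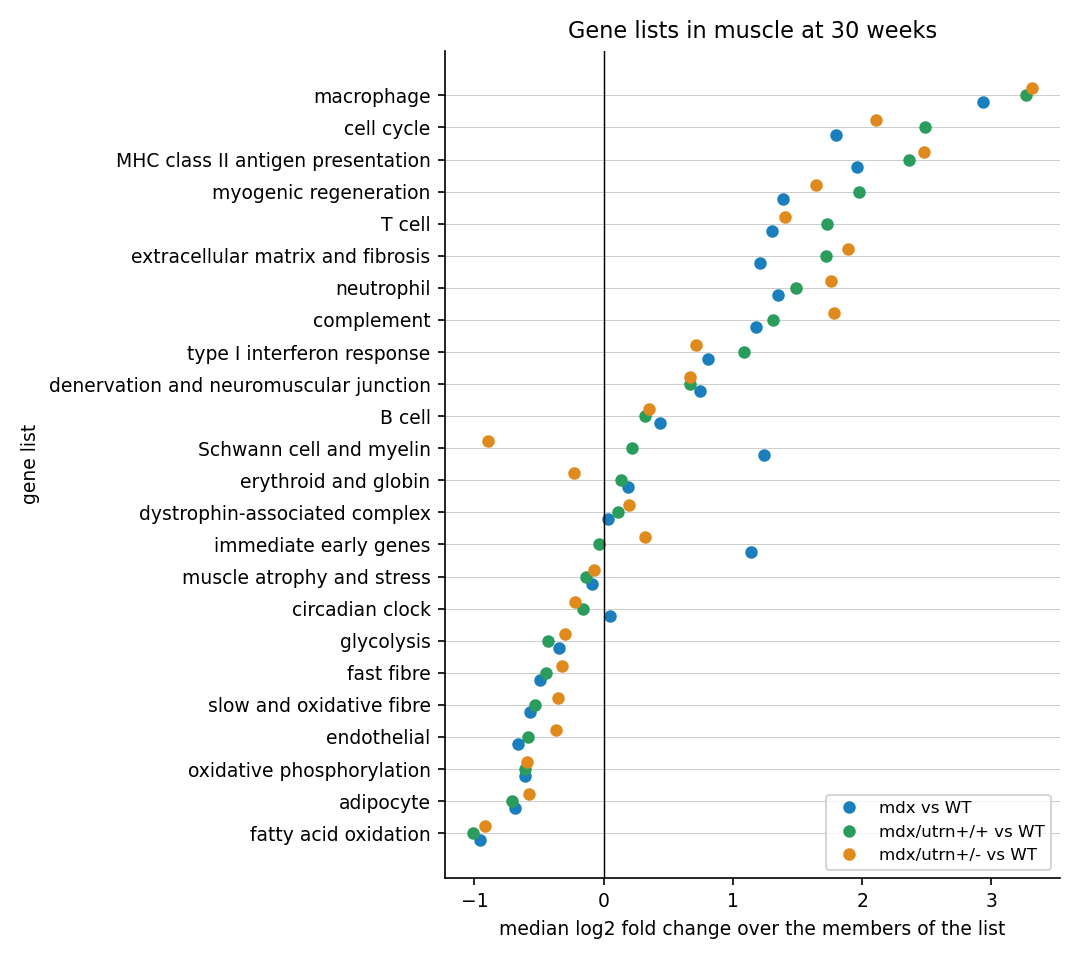
Median log2 fold change over the members of each gene list in 30-week muscle of mdx, mdx/utrn+/+ and mdx/utrn+/- mice, each against WT. The macrophage list has the highest medians and fatty acid oxidation lies at -0.96, -1.01 and -0.92.

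The 3 genotypes were compared for the genes they share. Genes called in the same direction numbered 6160 for mdx and mdx/utrn+/+, 5054 for mdx and mdx/utrn+/- and 5736 for mdx/utrn+/+ and mdx/utrn+/-, and none was called in opposite directions. Independence would give 1463 shared higher and 534 shared lower genes for the first pair, where 3812 and 2348 were found. In all 3 genotypes 2842 genes were higher and 2100 lower. The comparisons share the WT libraries: with the WT mice split so that each comparison had its own, the medians of 35 splits were 3475, 3052 and 3762 shared genes, and the correlations across genes were 0.90, 0.66 and 0.78 in this order of pairs (0.94, 0.69 and 0.82 unsplit). Simulated groups without a difference, set against the same WT libraries, had correlations of 0.55, 0.55 and 0.54 and no shared calls. These overlaps hold the libraries with abundant brain transcripts, mdx replicates 5 and 6 and mdx/utrn+/+ replicate 5, also with the WT mice split. Without them fewer genes were higher in mdx muscle in all than the 3812 shared here. The overlaps were not computed without them, so these values do not rank the pairs.

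**Figure D3:**
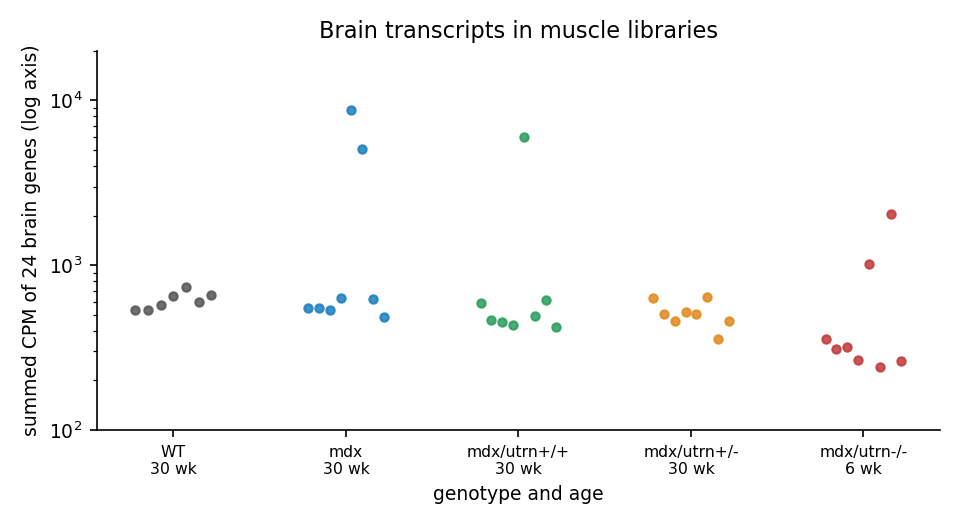
Summed CPM of 24 brain genes in each library of 30-week muscle and of 6-week mdx/utrn-/- muscle, by genotype, on a log axis; points are libraries. The highest are 2 mdx libraries and 1 mdx/utrn+/+ library at 5095 to 8730 CPM and 2 mdx/utrn-/- libraries at 1014 and 2040 CPM.

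Whether losing 1 copy of Utrn changes dystrophic muscle was asked by comparing mdx/utrn+/- with mdx/utrn+/+ muscle at 30 weeks (n = 8 each). By edgeR 1 gene passed: E030030I06Rik (chromosome 10, 22113050 to 22149270), a gene of unknown function, was higher in mdx/utrn+/- muscle by a log2 fold change of 4.82 ± 0.49 (adjusted p = 1.50e-06). Utrn lies on chromosome 10 too, so an effect of the lost copy cannot be told apart from one of DNA linked to it. Without adjustment 887 genes had p under 0.05, and DESeq2 called 2. No member of any of the 24 lists passed. Adjusted over the list alone, 6 of 13 Schwann cell and myelin genes, 1 T cell and 1 erythroid gene were lower. Without the libraries with abundant brain transcripts, 1 of them mdx/utrn+/+ replicate 5, these numbers were 0, 0 and 1. The type I interferon response list had a median of -0.42 (adjusted p = 0.233 with an estimated correlation; Ddx60 -0.61 ± 0.20, adjusted p = 0.501 by edgeR). In the library labelled mdx/utrn+/- replicate 5, E030030I06Rik was at 0.356 CPM, against 2.7 to 20.1 CPM in the other mdx/utrn+/- libraries. Without the libraries with abundant brain transcripts 2 genes passed, the second being Rab6b, a vesicle transport gene (2.84 ± 0.50, adjusted p = 0.0276 by edgeR), which was then lower in mdx/utrn+/+ than in WT and mdx muscle (-4.42 ± 0.52 and -3.98 ± 0.52). None passed in mice with blood libraries alone, which include the mouse of mdx/utrn+/- replicate 5.

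mdx/utrn+/+ and mdx mice, which both carry the Dmd mutation and intact Utrn, were compared to ask whether the lines differ. By edgeR, 2 genes passed in 30-week muscle (n = 8 each). Cd59b, a complement inhibitor gene (chromosome 2, 104069849 to 104091187), was lower in mdx/utrn+/+ muscle by edgeR (-2.60 ± 0.31, adjusted p = 4.69e-05). Also lower was Fv1, a viral restriction gene (chromosome 4, 147868979 to 147870358; -1.09 ± 0.19, adjusted p = 0.0219 by edgeR). The unadjusted count was 1124, and DESeq2 called 281 genes. No member of the 24 lists passed. Adjusted over the list alone, 7 of 30 interferon response genes were higher in mdx/utrn+/+ muscle (median 0.45, adjusted p = 0.214 with an estimated correlation). Of 18 immediate early genes 5 were lower (median -0.76, adjusted p = 0.214 with an estimated correlation), and 2 regeneration genes and 1 T cell gene were higher. Without the 3 libraries with abundant brain transcripts 27 genes passed, 12 higher and 15 lower, with Rab6b at -3.98 ± 0.52, and the count was 0 in mice without blood libraries, 11 in mice with them, 7 with all ages and 5 with the cohort as a covariate.

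For mdx/utrn-/- mice the only muscle libraries were from 6-week mice, so the comparison of mdx/utrn-/- (n = 8) with 30-week mdx/utrn+/+ muscle (n = 8) holds genotype and age together and these cannot be told apart in it. Genes of regeneration, matrix and the cell cycle were higher in the 6-week mdx/utrn-/- muscles. Of 23 regeneration genes 20 were higher (adjusted p = 0.105 with an estimated correlation), among them Myh3 (2.66 ± 0.33) and the growth factor gene Igf2 (2.15 ± 0.25). Of 31 matrix genes 26 were higher (adjusted p = 0.105 with an estimated correlation), among them Col12a1 (1.68 ± 0.18), and of 25 cell cycle genes 23 (adjusted p = 0.355 with an estimated correlation). Dlk1, a fetal growth gene, was 3.70 ± 0.90 higher (6.42 ± 0.30 without the libraries with abundant brain transcripts) and Postn (periostin) 2.96 ± 0.43. Macrophage genes were higher for 16 of 27 members (adjusted p = 0.437 with an estimated correlation), with Adgre1 at 1.56 ± 0.32. Genes of glycolysis were lower for 15 of 20 members and higher for 1, such as Pfkm, a phosphofructokinase (-1.21 ± 0.18), and genes of fast fibres for 13 of 19 (adjusted p = 0.437 and 0.606 with an estimated correlation). Lower were also 30 of 40 genes of oxidative phosphorylation and 13 of 26 of fatty acid oxidation (adjusted p = 0.489 and 0.688 with an estimated correlation). Of 18 circadian genes 11 were lower (adjusted p = 0.105 with an estimated correlation). Cdkn2a was lower (-2.41 ± 0.27). The complement list had 10 of 19 members higher, led by the macrophage receptor gene Vsig4 (2.74), and 2 lower, C7 and C3 (-2.58 and -2.01). Slow fibre genes were higher for 7 of 16 members and lower for 2 (adjusted p = 0.220 with an estimated correlation). In the B cell, Schwann cell and interferon lists 5 of 11, 4 of 13 and 4 of 30 genes were higher, and the T cell, adipocyte and dystrophin complex lists were split at 4 higher and 2 lower, 2 and 4, and 6 and 4. Of 14683 genes tested by edgeR 2345 were higher and 2993 lower. Without mdx/utrn+/+ replicate 5 and mdx/utrn-/- replicates 5 and 7, in which brain transcripts were abundant, 3737 were higher and 3353 lower, and with 30-week mdx/utrn+/- muscle as the other group 8145 passed.

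In blood, counts were summed per mouse over weeks 6 to 18 to compare genotypes (5 mice each). Of the 33 genes that separated mdx/utrn+/+ from WT blood, 25 were called in the same direction between mdx/utrn+/- and WT blood and 2 between mdx and WT blood, with the same WT mice in each comparison. Hpgd, which degrades prostaglandins (chromosome 8, 56294585 to 56321043), was higher by 4.07 ± 0.24 in mdx/utrn+/+ and 3.59 ± 0.23 in mdx/utrn+/- blood, in 5 of 5 mice of each. Tlr1, a receptor for bacterial lipoproteins (chromosome 5, 64924679 to 64933563), was lower (-2.86 ± 0.17 and -2.97 ± 0.18), as were Cd59b (-3.52 ± 0.42 and -3.44 ± 0.42) and its neighbour Cd59a (-2.67 and -2.73). Clstn1 (1.28 and 1.24), Pes1 (0.59 and 0.76) and Pik3ip1 (1.18 and 1.45) were higher. Chordc1, a partner of heat shock proteins (chromosome 9, 18292125 to 18317442), was lower in all 3 dystrophic genotypes (-1.11 ± 0.12, -1.05 and -1.04). In mdx/utrn+/- blood 1 list member passed, Siglecf, a receptor of eosinophils (-1.18 ± 0.22, adjusted p = 0.0232 by edgeR). Of 14823 genes, edgeR called 3 in mdx (1 higher and 2 lower), 33 in mdx/utrn+/+ (20 and 13) and 44 in mdx/utrn+/- blood (24 and 20); the other 2 in mdx blood were Naalad2, beside Chordc1 on chromosome 9 (-3.02), and 3110070M22Rik (1.23).

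Adjusted over the list alone, 10 of 30 interferon response genes (adjusted p = 0.478 with an estimated correlation), 6 of 23 neutrophil and 6 of 17 NK and cytotoxic genes were higher in mdx blood. Of 22 T cell genes 4 were then higher in mdx/utrn+/+ and 8 in mdx/utrn+/- blood (adjusted p = 0.384 and 0.511 with an estimated correlation), and 9 interferon response genes in mdx/utrn+/- blood. Between mdx/utrn+/- and mdx/utrn+/+ blood edgeR called 0 genes (179 at an unadjusted p under 0.05; DESeq2 3, limma-voom 7). Between mdx/utrn+/+ and mdx blood 18 passed (12 higher and 6 lower), with Hpgd (4.52 ± 0.25), Tlr1 (-2.61 ± 0.17) and Cd59b (-4.20 ± 0.43) as far apart as from WT. The counts differed by tool: limma-voom on all blood libraries with the mouse as a block called 145, 864 and 777 genes in mdx, mdx/utrn+/+ and mdx/utrn+/- blood and 121 between mdx/utrn+/+ and mdx, and DESeq2 31, 118, 167 and 44. Single mice moved them too. Without WT mouse 3 the mdx/utrn+/+ count was 12 and the mdx/utrn+/- count 25. The mdx/utrn+/+ count was 21 without WT mouse 5 and 20 without mdx/utrn+/+ mouse 5. The mdx/utrn+/- count was 24 or 26 without mdx/utrn+/- mouse 3 or 4. Without mdx mouse 1, 2, 3 or 4 the count between mdx/utrn+/+ and mdx was 10, 11, 10 or 10. The mdx count fell to 1 without any of WT mice 2 to 5 or mdx mice 1 to 5, and the mdx/utrn+/- against mdx/utrn+/+ count was 2 without mdx/utrn+/- mouse 5. That mouse also gave the 30-week muscle library labelled mdx/utrn+/- replicate 5, whose genotype is in doubt. E030030I06Rik, the gene called in muscle, was looked up in single blood libraries after that call was seen. It was at 6.81 to 15.7 CPM in the 18 libraries of the other mdx/utrn+/- mice. In the 21 libraries of mdx/utrn+/+ mice it was at 0.35 to 3.05 CPM. Several of these libraries are from the same mouse. The 0 calls thus do not show that blood of these genotypes is alike.

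**Figure D4:**
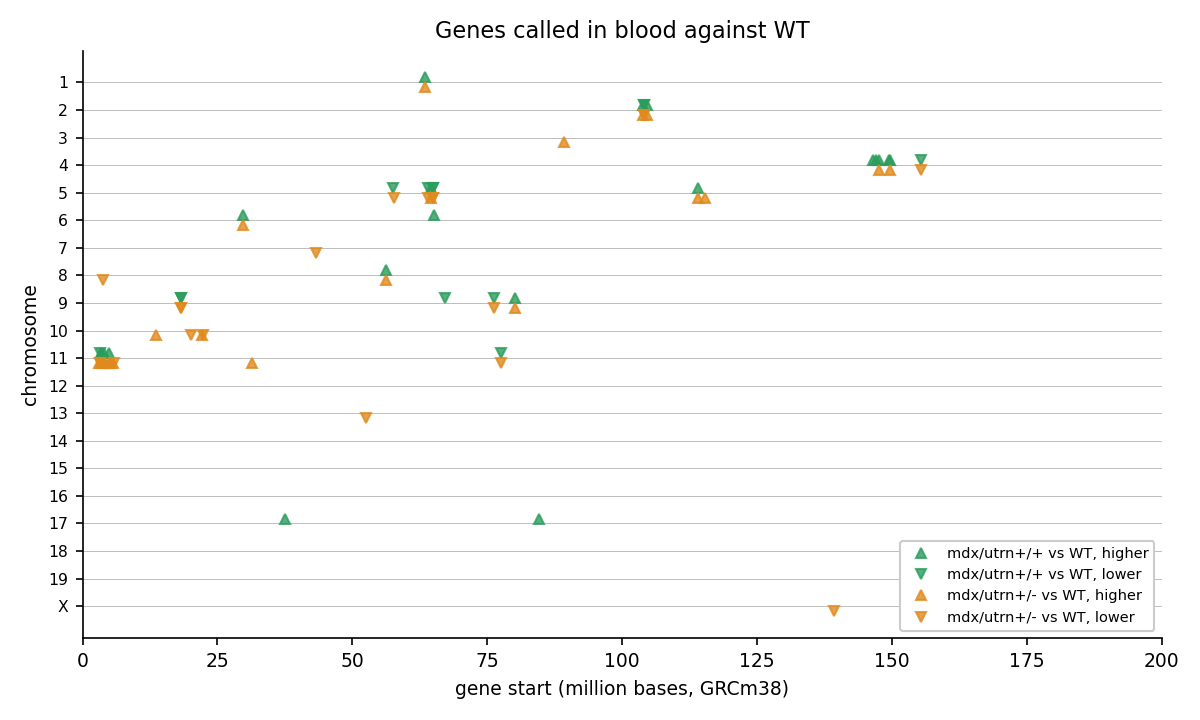
Position along each chromosome of the genes called in blood summed per mouse, against WT in mdx/utrn+/+ and mdx/utrn+/- mice. Each mark is 1 gene in 1 comparison. Marks gather in short segments, such as that of Tlr1 and Fam114a1 on chromosome 5 and that of Patz1, Pik3ip1 and Pes1 on chromosome 11.

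Differences of dystrophic from WT blood were asked week by week, with the mean of mdx, mdx/utrn+/+ and mdx/utrn+/- blood set against WT blood of the same age. Vcan (versican, a matrix proteoglycan made by monocytes) was higher in dystrophic blood, by 2.00 ± 0.35 at 18 weeks in 14 of 14 libraries, 2.60 ± 0.42 at 24 weeks in 9 of 9 and 2.25 ± 0.46 at 30 weeks in 11 of 11 (adjusted p = 0.0208, 0.00611 and 0.0330 by edgeR). At 6 and 12 weeks Vcan was at 1.02 ± 0.50 and 0.45 ± 0.55 and did not pass, and the interaction of age and genotype did not pass by edgeR ( 0.67 ± 0.91, adjusted p = 0.794). Siglecf was lower at 18 and 24 weeks (-1.28 ± 0.24 and -1.48 ± 0.16), with Il5ra (-0.53), the receptor by which eosinophils respond to interleukin, and at 24 weeks Ccr3, their chemokine receptor (-1.77 ± 0.28). At 6 weeks Ear1, of the eosinophil and basophil list, was higher (2.36 ± 0.39, adjusted p = 0.00693 by edgeR). Adjusted over the list alone, 4 of its 14 members were then higher and 3 lower. At 6 weeks the neutrophil granule genes Ltf (2.88 ± 0.53) and Ngp (2.51 ± 0.51) were higher, and 14 of 20 platelet genes when adjusted over the list alone (none over all genes; adjusted p = 0.428 with an estimated correlation). At 12 weeks no list member passed, and 8 of 30 interferon response genes did when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). At 18 weeks 11 interferon (adjusted p = 0.330 with an estimated correlation), 7 monocyte and 5 T cell genes passed in this way.

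At 24 weeks 7 of 26 monocyte genes rose (13 adjusted over the list alone), among them Ms4a6d (1.46) and the chemokine receptor gene Ccr2 (1.02), and 7 of 23 neutrophil genes, such as Chil3 (1.84 ± 0.26). Of 22 erythroid genes 7 rose, such as Bnip3l (1.20), with 7 of 20 platelet genes, such as Gp9 (1.24), and 6 of 25 ribosomal protein genes. Of 14 eosinophil and basophil genes 5 fell. For each of these lists adjusted p was 0.372 with an estimated correlation. Of 30 interferon response genes 7 rose and 1 fell (adjusted p = 0.580 with an estimated correlation). At 30 weeks 5 of 30 interferon response genes rose, 15 when adjusted over the list alone (median 0.47; adjusted p = 0.0777 with an estimated correlation and 0.0106 by fry). Oas2 was at 1.29 ± 0.23 (higher in 10 of 11 libraries) and Oasl1 at 1.18 ± 0.22. Of 26 monocyte genes 3 rose (adjusted p = 0.528 with an estimated correlation), Chil3 rose (1.99 ± 0.43), and 8 eosinophil and basophil genes were lower when adjusted over the list alone (adjusted p = 0.838 with an estimated correlation). Sdc1, the plasma cell syndecan, was lower at 18, 24 and 30 weeks (-0.91, -0.88 and -0.74). The plasma cell list was split. Adjusted over the list alone, 1 of 11 members was higher in each of these weeks, and 2, 2 and 3 were lower. Rab6b was lower at 24 and 30 weeks (-2.88 ± 0.30 and -2.68 ± 0.37). With the hour of collection as a covariate 6 genes in all passed at 30 weeks, so not all of these 30-week calls held.

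By edgeR 27 genes passed at 6 weeks (12 higher and 15 lower), 12 at 12 weeks (4 and 8), 16 at 18 weeks (6 and 10), 1444 at 24 weeks (782 and 662) and 111 at 30 weeks (26 and 85), where the mdx mice numbered 2 at 24 and 4 at 30 weeks. Of the 33 genes called between mdx/utrn+/+ and WT blood summed per mouse, such as Hpgd, Tlr1 and Cd59b, 9, 10, 10, 20 and 12 were called in the same direction in these weeks in turn. They are 9 of the 27, 10 of the 12 and 10 of the 16 genes of the first 3 weeks. Whether the weeks differ from each other was tested for weeks 6 and 30 alone, with the age comparison. DESeq2 called 511, 25, 98, 2426 and 419 genes. With the hour of collection as a covariate 17, 667 and 6 genes passed at 6, 24 and 30 weeks. At 6 weeks mdx replicate 5 was collected hours later than every other library (SD 2.86 hours in mdx). The 6-week covariate leans on this library, so it is a weak check on the hour. At 6 weeks the split of calls was 13 higher and 27 lower with RLE scaling. The counts leaned on single mice. At 6 weeks 9, 17 or 5 genes passed without WT replicate 1, 2 or 4, and 56 without mdx replicate 1. Without mdx/utrn+/+ replicate 2 the 6-week count was 14, and 72, 15 or 17 without mdx/utrn+/- replicate 2, 3 or 4. At 12 weeks 5 or 7 passed without WT replicate 2 or 5. At 18 weeks 8, 9 or 10 passed without WT replicate 3, 4 or 5, and 32 or 30 without mdx/utrn+/+ replicate 1 or 2. At 24 weeks 885, 928, 435 or 371 passed without WT replicate 1, 2, 3 or 4, and 875 or 367 without mdx replicate 1 or 2. At 30 weeks 21, 282, 329 or 460 passed without WT replicate 2, 3, 4 or 5, and 55, 64 or 52 without mdx replicate 2, 3 or 4. The 30-week count was 50 or 53 without mdx/utrn+/+ replicate 2 or 3 and 50, 170, 58 or 62 without mdx/utrn+/- replicate 1, 2, 3 or 4.

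Blood of 6-week mdx/utrn-/- mice was compared with WT and with mdx/utrn+/+ blood of that age (n = 5 each). Utrn did not pass by edgeR in either comparison (0.04 ± 0.15 and 0.17 ± 0.15, adjusted p = 0.877 and 0.505), so the counts of this gene in blood do not bear out the genotype. Red cell and platelet genes were higher in mdx/utrn-/- blood. All 22 measured erythroid genes were higher than in WT (median 2.43; adjusted p = 0.240 with an estimated correlation and 0.0105 by fry). Among them were Gata1, the erythroid transcription factor (1.63 ± 0.35, in 5 of 5 mice), and Tfrc, the transferrin receptor (1.11 ± 0.25). Of 20 platelet genes 18 were higher (median 1.52; adjusted p = 0.228 with an estimated correlation), such as Gp5 (2.12 ± 0.40). Of 25 cell cycle genes 15 were higher and 1 lower (adjusted p = 0.228 with an estimated correlation), with Mki67 at 2.71 ± 0.50. Lower were 10 of 19 B cell genes (Cd22 -0.97 ± 0.20; adjusted p = 0.240 with an estimated correlation) and 7 of 12 genes of MHC class II antigen presentation (Ciita -1.02 ± 0.20; adjusted p = 0.228 with an estimated correlation). Also lower were 6 of 14 eosinophil and basophil genes (Ccr3 -2.24 ± 0.33; 1 higher), 7 of 26 monocyte genes (1 higher) and 4 of 10 plasma cell genes. Of 23 neutrophil genes 4 were higher, among them Ltf (3.72 ± 0.60; adjusted p = 0.616 with an estimated correlation), and the interferon response list was split, 5 higher (Rsad2 2.87 ± 0.77) and 5 lower (Mx1 -1.23 ± 0.35). Of 10 fast fibre and 17 circadian genes 3 each were higher (medians 0.68 and 0.48; adjusted p = 0.534 and 0.822 with an estimated correlation). Against mdx/utrn+/+ 7 of 22 erythroid genes were higher, 17 when adjusted over the list alone (median 1.63; adjusted p = 0.397 with an estimated correlation), with 5 cell cycle genes and 1 platelet gene. Lower than in mdx/utrn+/+ were 4 interferon response genes (Mx1 -1.40 ± 0.35; adjusted p = 0.440 with an estimated correlation), 5 monocyte and 3 eosinophil and basophil genes.

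By edgeR, of 13692 genes 2047 were higher and 1116 lower than in WT, and 735 higher and 395 lower than in mdx/utrn+/+ blood. The ribosomal precursor Rn45s was among the most raised genes (log2 fold changes 5.87 ± 1.06 and 5.33 ± 1.03), and it held 52.05% of the gene fragments of mdx/utrn-/- replicate 4 and 2.11 to 15.7% in the other 4. Without Rn45s 3158 and 1099 genes passed. With only the compared groups in the fit 1670 and 91 passed, and with the hour of collection as a covariate 329 against mdx/utrn+/+. The latter fit holds the late 6-week mdx library given above. The count against WT was 2048 without WT replicate 4. That against mdx/utrn+/+ was 715, 479 or 394 without mdx/utrn+/+ replicate 2, 3 or 4. It was 1914, 1914 or 601 without mdx/utrn-/- replicate 1, 2 or 4.

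**Figure D5:**
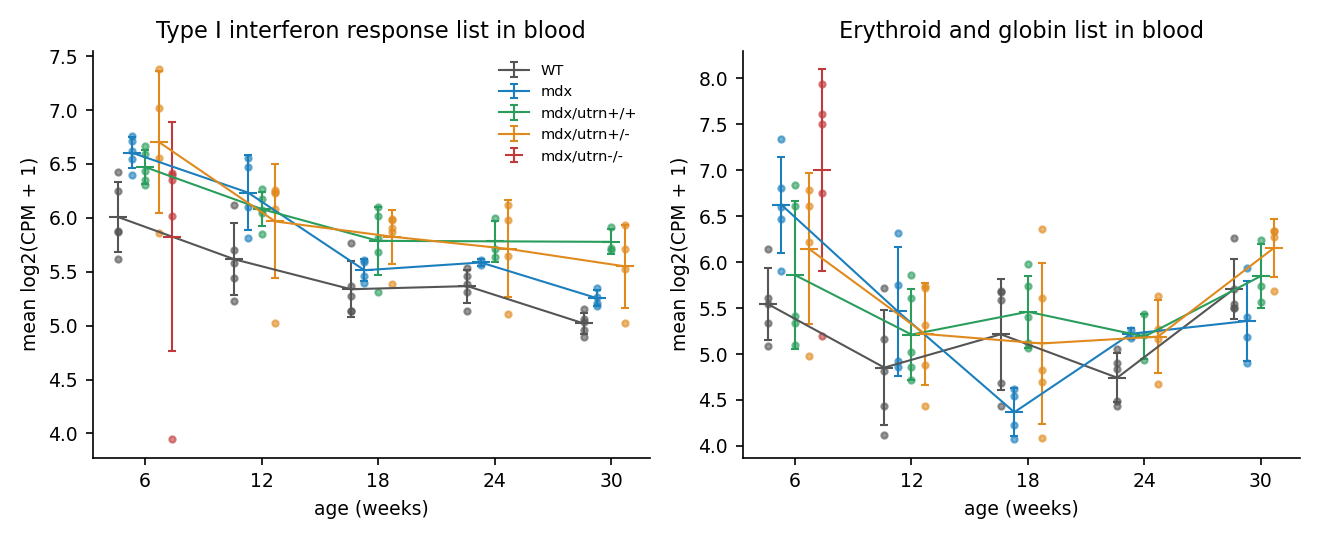
Mean log2(CPM + 1) over the members of the type I interferon response list and of the erythroid and globin list in each blood library, by genotype and age in weeks. Points are libraries, lines and bars the mean and its SD per group. The interferon list falls in WT from 6.01 at 6 weeks to 5.02 at 30 weeks and in mdx from 6.61 to 5.25, and the 5 mdx/utrn-/- libraries have the highest mean of the erythroid list at 6 weeks (WT 5.54).

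Aging in blood was followed in the mice bled at both 6 and 30 weeks, with the mouse as a block (5 WT and 10 dystrophic mice). Interferon response genes fell with age in both: 23 of 30 in WT (median -1.08; adjusted p = 0.134 with an estimated correlation and 9.19e-04 by fry) and 27 of 30 in dystrophic mice (median -1.12; adjusted p = 0.0132 with an estimated correlation). Ddx60, an interferon-induced helicase gene, changed by -1.59 ± 0.20 in WT and -1.41 ± 0.13 in dystrophic mice, lower in 5 of 5 and 10 of 10 mice. T cell genes fell for 9 of 22 members in WT (adjusted p = 0.803 with an estimated correlation) and 18 in dystrophic mice (adjusted p = 0.102 with an estimated correlation), with Cd4 at -0.62 ± 0.13 and -1.10 ± 0.10. In dystrophic mice 11 of 19 B cell genes (Cxcr5 0.81 ± 0.13; adjusted p = 0.434 with an estimated correlation) rose, and 9 of 12 genes of MHC class II antigen presentation (H2-Ab1 0.90 ± 0.16; adjusted p = 0.139 with an estimated correlation) rose too. Lower with age were 4 of 23 neutrophil (Ltf -2.93 ± 0.44; adjusted p = 0.434 with an estimated correlation), 7 of 17 NK and cytotoxic and 5 of 20 platelet genes. In WT mice 3 genes of MHC class II antigen presentation rose and 1 fell, 7 of 17 circadian genes rose (Hlf 1.82; adjusted p = 0.803 with an estimated correlation). In dystrophic mice 4 circadian genes rose and 1 fell (adjusted p = 0.454 with an estimated correlation). The hour of collection was later at 30 than at 6 weeks in 5 of 5 WT and 5 of 10 dystrophic mice. In WT mice it cannot be told apart from age, for circadian or any other genes. The difference between dystrophic and WT mice in the change with age holds this imbalance too. In WT mice 5 NK and cytotoxic genes fell and 1 rose, and the basophil genes Fcer1a (2.44 ± 0.54) and Mcpt8 (2.17 ± 0.56) rose. Utrn fell with age in both (-0.67 ± 0.17 and -0.50 ± 0.12).

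By edgeR, of 13733 genes 997 rose and 994 fell in WT and 1463 rose and 1190 fell in dystrophic mice. The paired difference between dystrophic and WT mice in the change with age was tested as an interaction, and 0 genes passed by edgeR (1461 at an unadjusted p under 0.05; DESeq2 61). In the interaction camera with the preset correlation called the platelet, erythroid, B cell, T cell, MHC class II and cell cycle lists (medians -0.81, -0.69, 0.26, -0.18, 0.23 and -0.27; adjusted p = 3.30e-08, 0.00106, 0.00392, 0.00864, 0.0112 and 0.0156). With an estimated correlation adjusted p was 0.775 for each of them. Without the replicate block 3060 genes passed in WT and 3191 in dystrophic mice. The WT count was 903 or 325 without WT mouse 2 or 4. The dystrophic count was 1678 without mdx/utrn+/+ mouse 3 and 1733 without mdx/utrn+/- mouse 2. The interaction called 1 gene without WT mouse 1, mdx/utrn+/+ mouse 1 or mdx/utrn+/- mouse 1.

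Calls were compared between tissues over 13239 genes tested in both. Genes called in the same direction in muscle and blood numbered 1 in mdx, 11 in mdx/utrn+/+ (8 higher and 3 lower) and 14 in mdx/utrn+/- mice (10 and 4), and 4 and 6 were called in opposite directions in the latter genotypes. Independence would give 4.35 higher and 2.08 lower genes in mdx/utrn+/+ and 4.71 and 3.24 in mdx/utrn+/- mice, but the tissues share 24 mice, so calls in them are not independent and chance sharing was not estimated. By DESeq2 11, 39 and 54 genes were called in the same direction in mdx, mdx/utrn+/+ and mdx/utrn+/- mice, and 5, 23 and 23 in opposite directions. Independence would then give 5.67, 15.8 and 20.4 shared higher and 0.837, 8.31 and 11.7 shared lower genes.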

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

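The 2 tests of chromosome 10 were planned, and the other tests given here (those of brain RNA, dystrophic genotype, mislabelling, crossover, strain variants and a response to missing dystrophin, and the splits of the samples) were chosen after the results were seen.

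A single library stood far from the rest of its group in 13 sets of libraries and measures, where chance gives about 6.9 (1 in 20 of those examined). In muscle, Dmd was at 75.7 CPM in mdx replicate 3 (46.4 to 57.4 in the other 30-week mdx libraries), Utrn at 81.8 CPM in WT replicate 3 (50.5 to 63.9), and the brain genes summed to 5976 CPM in mdx/utrn+/+ replicate 5 (424 to 612) and 2040 CPM in mdx/utrn-/- replicate 7 (241 to 1014). The ribosomal precursor Rn45s held 1.95% of the gene fragments of mdx/utrn-/- replicate 6 (0.420 to 0.888% in the others) and 2.07% of mdx replicate 5 (0.238 to 0.960%). In blood it held 52.05% of mdx/utrn-/- replicate 4 (2.11 to 15.7%), 6.39% of mdx/utrn+/- replicate 3 at 6 weeks (1.22 to 1.86%), 4.59% of mdx replicate 4 at 12 weeks (1.21 to 1.52%) and 6.79% of mdx/utrn+/- replicate 2 at 30 weeks (1.57 to 2.11%). Bone and tendon genes summed to 203 CPM in WT replicate 5 at 24 weeks (29.2 to 45.4 CPM in the others) and 171 CPM in mdx/utrn+/+ replicate 1 at 12 weeks (37.3 to 54.1 CPM). E030030I06Rik was at 3.66 CPM in WT blood replicate 4 at 30 weeks (1.49 to 2.09 CPM).

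In 5 muscle libraries (mdx replicates 5 and 6, mdx/utrn+/+ replicate 5 and mdx/utrn-/- replicates 7 and 5) 24 brain genes summed to 8730, 5095, 5976, 2040 and 1014 CPM, against 241 to 741 CPM in the other 43, where Camk2a, a gene of muscle too, had a median of 465.7 CPM and 5 of the 24 a median over 1 CPM. The 5 libraries are of dystrophic genotypes, and a part of the genotype cannot be told apart from chance, since at most 2 libraries of each genotype stand out and its median cannot move (0 of 4 medians above the highest WT library). In each of the 5 at least 21 of the 24 genes, neuronal and glial, lay above the highest of the other 43 libraries, with Snap25 at 75.2 to 1232 CPM (at most 1.01 in the others), Slc1a2 at 170.6 to 1462 CPM (at most 1.09) and Mobp at 22.7 to 144.7 CPM (at most 0.166). A candidate explanation that stays open is RNA from brain tissue in these muscle samples or libraries, and how it would have come there was not tested.

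In the library labelled mdx/utrn+/- replicate 5 of 30-week muscle, E030030I06Rik was at 0.356 CPM, where the other 7 mdx/utrn+/- libraries lay at 2.73 to 20.1 CPM and mdx/utrn+/+ libraries at 0.164 to 0.509 CPM. A crossover between Utrn and E030030I06Rik would have kept the Utrn level of the genotype, but Utrn was at 54.3 CPM, above the other mdx/utrn+/- libraries (31.2 to 45.7 CPM, mean 37.8 and SD 4.25) and within mdx/utrn+/+ (42.7 to 56.8 CPM). In the 4 blood libraries of the same mouse E030030I06Rik lay at 1.73 to 3.64 CPM, below the 6.81 to 15.7 CPM of the other 18 mdx/utrn+/- blood libraries. The 21 mdx/utrn+/+ blood libraries lay at 0.35 to 3.05 CPM. The 12-week mdx/utrn+/- muscle, given below, had E030030I06Rik close to the highest mdx/utrn+/+ library but Utrn within the other mdx/utrn+/- libraries. That is the pattern a crossover would give, so E030030I06Rik alone, in muscle or blood, does not settle the Utrn genotype. A mislabelled sample, a mouse with 2 intact copies of Utrn, is a candidate explanation that stays open, and no biological explanation other than the crossover was tested. Without this library 6057 genes passed in mdx/utrn+/- against WT muscle, and E030030I06Rik was the gene called against mdx/utrn+/+ (5.00 ± 0.38). In blood summed per mouse, leaving this mouse out gave 2 genes by edgeR between mdx/utrn+/- and mdx/utrn+/+ (0 with it).

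Of the 33 genes called between mdx/utrn+/+ and WT blood, 22 had another of them within 5000000 bases, where 10000 random draws of as many tested genes gave a median of 6 and at most 17 (permutation p = 1.00e-04, the smallest these draws can give). A blood response to missing dystrophin would appear in mdx blood as well, but there the log2 fold changes were a median of 0.112 of those in mdx/utrn+/+ blood (quartiles 0.0227 and 0.487), and 25 of 33 had the same direction. Against mdx blood, which lacks dystrophin too, 15 of the 33 were called in the same direction in mdx/utrn+/+ blood. Strain variants in DNA segments that differ between the lines are a candidate explanation that stays open, for which 13 of the 18 genes called between mdx/utrn+/+ and mdx blood and 31 of the 44 between mdx/utrn+/- and WT blood had such a neighbour (permutation p = 1.00e-04 for both). These results are not separate from the first, since 15 of the 18 and 25 of the 44 are among the 33 and the comparisons share mice. In mdx/utrn+/+ against mdx muscle 1 of 25 of the genes was called in the same direction (median ratio 0.140) and 0 of the 2 called genes had such a neighbour (permutation p = 1). With only these 2 genes, which lie on different chromosomes, the latter result was fixed and does not bear on the explanation. Whether variants change expression or how fragments map was not tested.

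DNA linked to Utrn on chromosome 10, where 4.92% of the genes tested in muscle lie, was tested in the 2 comparisons of Utrn genotypes. The 1 gene called between mdx/utrn+/- and mdx/utrn+/+ muscle, E030030I06Rik, lies on it (one-sided Fisher exact p = 0.0492, and 0.0491 without the library labelled mdx/utrn+/- replicate 5), and with 1 gene this p is the share of the chromosome. In 6-week mdx/utrn-/- muscle this gene was at 1.53 to 4.18 CPM, above 30-week WT (0.139 to 0.646 CPM), mdx (0.204 to 0.464 CPM) and mdx/utrn+/+ muscle (0.164 to 0.509 CPM). It was thus higher in both groups with a Utrn knockout than in these 30-week groups, though not in every library. The median was 2.43 CPM in mdx/utrn-/- and 6.90 CPM in the other 30-week mdx/utrn+/- libraries, without replicate 5. The mdx/utrn-/- muscles are of 6 weeks and no group without a knockout is of that age, so age and genotype are joined there. Linked DNA and the loss of Utrn itself cannot be told apart by these values. In mdx/utrn-/- against mdx/utrn+/+ blood 57 of 1127 called genes lay on chromosome 10 (5.06%, against 4.86% of tested genes; one-sided Fisher exact p = 0.394), and linked DNA cannot be told apart from other causes there, since a few linked genes would not move this share.

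The libraries or mice of each comparison were split anew into groups of the same sizes, 100 splits with the real one included. Each comparison was read alone, without adjusting for their number. Chance can be excluded for mdx, mdx/utrn+/+ and mdx/utrn+/- against WT muscle (7520, 7349 and 6328 genes, with at most 2576, 4315 and 2666 in the other splits) and for 6-week mdx/utrn-/- against 30-week mdx/utrn+/+ muscle (5338 and 3506). For mdx/utrn+/- against mdx/utrn+/+ muscle 4 of 100 splits called 1 gene or more (1 and 1). This share is under 0.05, but other splits matched the real count, so the count does not exclude chance. For mdx/utrn+/+ against mdx muscle the splits cannot exclude chance, since 21 of 100 called as many genes (2, and at most 4650). They held mdx replicates 5 and 6 and mdx/utrn+/+ replicate 5, in which brain transcripts were abundant. No splits were fitted without these libraries, so the splits do not decide on the genes called. Whether these libraries make the splits with so many calls was not tested.

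In blood per mouse chance can be excluded for mdx/utrn+/+ against WT (33 genes, at most 1 in the other splits), mdx/utrn+/- against WT (44 and 34) and mdx/utrn+/+ against mdx (18 and 1). It cannot be excluded for mdx against WT, where 5 of 100 splits called as many (3 and 177). For mdx/utrn+/- against mdx/utrn+/+ the splits cannot decide, since every split reaches a real count of 0 (100 of 100, at most 251; 179 genes at an unadjusted p under 0.05 by edgeR). What made the splits with 177 and 251 genes call so many was not tested.

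For dystrophic against WT blood chance can be excluded at 6 weeks (27 genes, at most 10 in the other splits), 12 weeks (12 and 1), 24 weeks (1444 and 1074) and 30 weeks (111 and 9). At 18 weeks 4 of 100 splits were as large (16 and 2642). This share is under 0.05, but other splits matched or passed the real count, so the count does not exclude chance. What made a split call 2642 genes was not examined. For 6-week mdx/utrn-/- blood the real count was the largest of 100 splits against WT (3163 and 3090) and mdx/utrn+/+ (1130 and 1080). The highest other split came near it in both, so the counts do not clearly exclude chance. What made those splits call so many genes was not examined. Change with age in dystrophic mice was set against exchanges of the 2 ages within mice, and chance can be excluded (2653 and 3). For WT mice 16 such exchanges are too few for a share under 0.05 (1991 and 272). For the difference between dystrophic and WT mice in the change with age the splits cannot decide, since every split reaches a real count of 0 (100 of 100 by edgeR, at most 0; 1461 genes at an unadjusted p under 0.05).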

How the results depend on the processing

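The fits without the 3 libraries with brain transcripts, without the library labelled mdx/utrn+/- replicate 5, without these 4 libraries, and without Rn45s were chosen after seeing the data; the others were planned. Apart from leaving out mice, 117 of 170 recomputed counts stayed within 1.5 times the reported one. Of 13857 values of named genes under an alternative, 12847 kept their direction and their side of the threshold, 880 kept their direction and no longer passed, 119 kept it and passed only then, and 11 turned. None of the others was left out, and genes missing from the authors' log2 CPM had no value by limma-trend. Where a cause is not given below, the cause was not tested. Smaller parts of the mice and groups fitted alone hold fewer samples by construction.

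In mice with muscle libraries only, 974, 2560 and 1860 genes passed in mdx, mdx/utrn+/+ and mdx/utrn+/- muscle against WT. In mice with blood libraries 4070 passed in mdx/utrn+/+ muscle, and limma-trend called 4783 in mdx muscle. For mdx/utrn+/- against mdx/utrn+/+ muscle the count was 2 by DESeq2, with all ages, without the 3 libraries with brain transcripts and without these 4 libraries, and 0 by limma-trend and in mice with blood libraries. For mdx/utrn+/+ against mdx muscle it was 281 by DESeq2, 5 with the cohort as covariate, 11 in mice with blood libraries, 0 in mice with muscle libraries only, 7 with all ages, 1 with only the compared groups or by limma-trend, and 27 without the 3 libraries with brain transcripts. Against mdx/utrn+/- at 30 weeks, 8145 genes passed in mdx/utrn-/- muscle.

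In blood per mouse, in the order mdx, mdx/utrn+/+ and mdx/utrn+/- against WT, mdx/utrn+/- against mdx/utrn+/+ and mdx/utrn+/+ against mdx, DESeq2 called 31, 118, 167, 3 and 44 genes and limma-voom 145, 864, 777, 7 and 121. The mdx count was 1 with no filter and 0 with only the compared groups, and the last count 6 with only the compared groups. By week from 6 to 30, DESeq2 called 511, 25, 98, 2426 and 419 genes and limma-voom 335, 36, 29, 599 and 71. With the hour of collection as covariate 17, 667 and 6 genes passed at 6, 24 and 30 weeks, and with no filter 174 at 30 weeks. For mdx/utrn-/- blood 1670 genes passed against WT and 91 against mdx/utrn+/+ with only the compared groups, and against mdx/utrn+/+ 1763 by DESeq2 and 329 with the hour of collection. With no replicate block 3060 genes changed with age in WT blood, and DESeq2 called 61 in the interaction. With the WT mice split, the muscle overlaps were 3475, 3052 and 3762, and DESeq2 gave a sum of 104 genes shared by muscle and blood over the 3 genotypes (26 by edgeR), in which a gene shared in 2 genotypes counts 2 times.

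Leaving out 1 mouse or library, 119 of 187 counts stayed within 1.5 times. In blood per mouse the counts ranged from 1 to 2, 12 to 34, 24 to 61, 0 to 2 and 10 to 22 in the above order. By week they ranged from 5 to 72, 5 to 13, 8 to 32, 367 to 2009 and 21 to 460. They ranged from 2048 to 4227 and 394 to 1914 in mdx/utrn-/- blood against WT and mdx/utrn+/+, and with age from 325 to 2468 in WT, 1678 to 2870 in dystrophic mice and 0 to 1 in the interaction.

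With an estimated correlation, camera kept a call of the interferon response in 1 comparison, and of each other list in 0. The preset correlation had called the interferon response in 17 comparisons, neutrophil genes in 16, B cell in 15, MHC class II in 14, and T cell and cell cycle genes in 13. Fry called the B cell list in 7 comparisons, the interferon and cell cycle lists in 6, the T cell and MHC class II lists in 5, neutrophil genes in 4, glycolysis, fatty acid oxidation, erythroid, and eosinophil and basophil genes in 3, immediate early and platelet genes in 2, slow fibre, NK, monocyte and ribosomal protein genes in 1, and muscle atrophy in 0. It called circadian genes in 6 comparisons, regeneration, matrix, macrophage, fast fibre, oxidative phosphorylation, complement and Schwann cell genes in 4, neuromuscular junction, adipocyte and endothelial genes in 3, dystrophin complex and plasma cell genes in 1, and keratinocyte genes in 0.

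Snap25 in mdx muscle was at -0.22 by DESeq2, -0.33 in mice with muscle libraries only and -0.58 without the 3 libraries with brain transcripts, where Slc1a2 was at -0.83 and -0.35 in the latter settings; the 2 mdx libraries with brain transcripts carry their rise. Ttr in mdx/utrn+/+ muscle was at -1.04 by DESeq2 and -2.58 in mice with blood libraries. With all ages Hspa1a and Hspa1b were at 0.54 and 1.07 there. Without mdx/utrn-/- replicate 1, the clock gene Ciart in mdx/utrn-/- blood was at -0.15 against WT and -0.0206 against mdx/utrn+/+, and without replicate 3 at 1.85 and 1.97. The smallest blood libraries at 12, 18 and 30 weeks hold 1906342, 3073420 and 3309612 fragments. Without each of them 10, 13 and 121 genes passed in its week (12, 16 and 111 with it), and what depth limits was not tested further.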

Other observations

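The genes of the imprinted cluster on chromosome 12 in 6-week mdx/utrn-/- muscle and the sums of bone genes were examined after their values were seen, and no explanation was tested for the values given here. Without the libraries in which brain transcripts were abundant, 5 of the 8 largest rises among named genes were of the imprinted cluster of Dlk1 and Meg3, in the comparison of 6-week mdx/utrn-/- with 30-week mdx/utrn+/+ muscle: Dlk1 (6.42 ± 0.30), AF357359, a small nucleolar RNA within Rian (3.31 ± 0.29), Rian (3.28 ± 0.27), Mirg (3.21 ± 0.18) and Meg3 (3.18 ± 0.29). Age and genotype are joined in that comparison. In the same fit Inmt (-3.39), Amy1 (-2.91), C7 (-2.62) and Cdkn2a (-2.40) were among the largest falls.

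Genes of bone and its matrix were among the largest falls with age in dystrophic blood: Col1a2 (-2.77 ± 0.59), Spp1 (osteopontin, -2.54 ± 0.41), Col1a1 (-2.22 ± 0.60) and Sparc (-2.18 ± 0.49). In WT blood Spp1 fell too (-2.88 ± 0.59). The difference between dystrophic and WT mice in these changes did not pass for any gene by edgeR. Between weeks, genes called in dystrophic against WT blood were shared in the same direction by 44 genes at 24 and 30 weeks (17 higher and 27 lower), and by 14 at 6 and 24 weeks. None was called in opposite directions in any pair of weeks, and the same mice were bled in each week, so that chance sharing is not given by independence and was not estimated.

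The 9 muscle libraries of other ages belong to no compared group. Dmd was at 252.9 and 190.8 CPM in WT muscle of 12 and 18 weeks, and between 37.4 and 84.4 CPM in the 7 dystrophic libraries. Utrn was at 91.5 and 58.9 CPM in these WT muscles, 56.8 and 48.2 CPM in mdx of 12 weeks, 49.4 and 42.4 CPM in mdx/utrn+/+ of 18 weeks, and 40.7, 40.8 and 37.7 CPM in mdx/utrn+/- of 6, 12 and 18 weeks. E030030I06Rik was at 14.8, 0.511 and 2.23 CPM in these 3 mdx/utrn+/- libraries and at 0.253 to 0.551 CPM in the other 6. Their brain genes summed to between 283 and 627 CPM.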
